A study of Homo sapiens with 2 samples.

How the data were processed

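The data were 2 RNA sequencing libraries of SW480 colorectal cancer cells, 1 from cells with a control vector and 1 from cells with an STC2 overexpression vector. Per the labels' protocols, total RNA was isolated with a column kit, made into stranded mRNA libraries with the TruSeq kit and sequenced on an Illumina HiSeq instrument. The submitters' processing notes name HISAT2 2.0.4 and the hg19 genome build. The program that computed the expression values, and its annotation, are not given in the sources used here.

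The values are FPKM, per the file headers, which the authors computed from their alignments: fragments scaled to the length of the transcript and to the mapped fragments of the library. The table lists 12218 genes in 1 column per library. The column for the control is headed only N, and was taken as the control library because N is the initial of its title's suffix and of its treatment label and fits nothing in the other sample's labels. The column headed STC2 was taken as the library labelled STC2 overexpression. The lowest value of a gene's higher library was 0.50 FPKM, so weaker genes were absent from the table, and 12149 rows are protein-coding in the annotation. No counts were used here, so the depth is unknown and no counting interval can be given for a gene's level. Genes at exactly 0 are reported as listed at 0, with no fold, because genes used by nearly all cells were among them.

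The values were used as deposited. The fold of each gene is the difference of log2(FPKM + 1) between the library labelled STC2 overexpression and the control library. With 1 library per group there is no estimate of spread, so genes were counted by a fixed rule of size, a fold of at least 2 with at least 1 FPKM in at least 1 library. For each gene list, the median log2 fold of members with a mean of at least 1 FPKM was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. This percentile describes these libraries and is no p-value. A list stood apart when its median lay outside the central 95% of the random medians, and lists with fewer than 3 measured members were given as values.

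The rule of size, the lists and the genes to be named were fixed before the data were examined. Named genes were STC2, the 14 genes with the largest and the 14 with the smallest log2 fold among genes with at least 5 FPKM in the higher library, and, for each list described, up to 4 members, the 2 highest and the 2 lowest. Some genes that the rule names are not reported here. After the values had been seen, the exon structure of each gene was taken from GENCODE release 29, as the share of the longest annotated transcript that its longest exon makes up. It was found for 12162 rows (99.5%) by gene identifier. That annotation is on another genome build than hg19, so it was used only for exon numbers, gene type and chromosome, and no coordinates are given. The naming rule was then repeated on genes above 0 in both libraries with a longest exon of at most 50% of the transcript. For the number of 2-fold members of a list, also added later, 10000 random lists were matched on expression and on the longest-exon share.

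Alternatives fixed beforehand were pseudocounts of 0.1 and 5 FPKM, no filter or one at 5 FPKM, scaling by the median ratio or the upper quartile, a 1.5-fold rule, list members with a mean of at least 5 FPKM, and random lists without matching. Median ratio scaling multiplied the library labelled STC2 overexpression by 0.984 and upper quartile scaling by 0.989. Alternatives added after seeing the data were the limit on the longest exon, the restriction to genes above 0 in both libraries, random lists matched also on the longest-exon share, and the other pseudocounts and scalings for the number of 2-fold members of each list.

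The counting rule and the list percentile were tested on simulated data for the comparison of the library labelled STC2 overexpression with control. All 12218 rows were simulated from the control values with a log2 ratio of SD 0.2, and 200 genes were changed, 50 per fold size. The rule recovered 34% of genes simulated at exactly 2-fold, which lies at the threshold and is reduced by the pseudocount, and 100% at 3-fold, 4-fold and 8-fold, and it took in 0 of 10658 unchanged genes. Of 200 unchanged lists of 20 genes, 4% lay outside the central 95%, and all lists shifted by 0.3 on the log2 scale lay above it. The simulated spread was set by choice, since the data hold no replicates from which to take it. It lies under the SD of the log2 folds in these data. That SD was 0.55 over the genes counted and 0.28 among those with a longest exon of at most 50% of the transcript. The simulation also made no gene 0 in only 1 library. The 0 of 10658 thus gives no rate of false calls for these data, and the shares recovered hold for the simulated spread only. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.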

Results

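Gene expression was measured by RNA sequencing in SW480, an established human colorectal cancer cell line. One culture had received a control vector and the other a vector for STC2, the gene of the secreted glycoprotein stanniocalcin 2. Each group had 1 library, so no difference given here has a replicate check, and no test or p-value is reported. The table held FPKM values for 12218 genes, of which 11136 reached 1 FPKM in at least 1 library. Read counts were not used here, so the depth behind each value is unknown. The FPKM values summed to 147966 in the control library and to 153983 in the library labelled STC2 overexpression, with medians of 4.94 and 5.03 FPKM.

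The comparison asks which genes differ in expression when STC2 is overexpressed. STC2 (ENSG00000113739, chromosome 5) was at 39.9 FPKM in the control library and at 42.6 FPKM in the library labelled STC2 overexpression, a ratio of 1.07 and a log2 fold of 0.09. It already ranked above 94.9% of the listed genes in the control library and above 95.2% in the other. The level of the gene thus does not tell the libraries apart by the 2-fold rule of size used here, and every direction below is that of the library labelled STC2 overexpression relative to the library labelled control. "Higher" and "lower" describe these libraries.

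Most genes were close to equal in both libraries. The middle 50% of the log2 folds lay between -0.11 and 0.14, and the central 95% between -1.14 and 1.17, with a median of 0.01. Across genes, which are not independent replicates, log2(FPKM + 1) correlated with a Pearson r of 0.935 and a Spearman coefficient of 0.930. By the rule of size, 350 genes (3.14%) were at least 2-fold higher in the library labelled STC2 overexpression and 345 (3.10%) were at least 2-fold lower, so neither direction prevailed. The folds are on the log2(FPKM + 1) scale, which understates differences of weakly expressed genes.

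**Figure D1:**
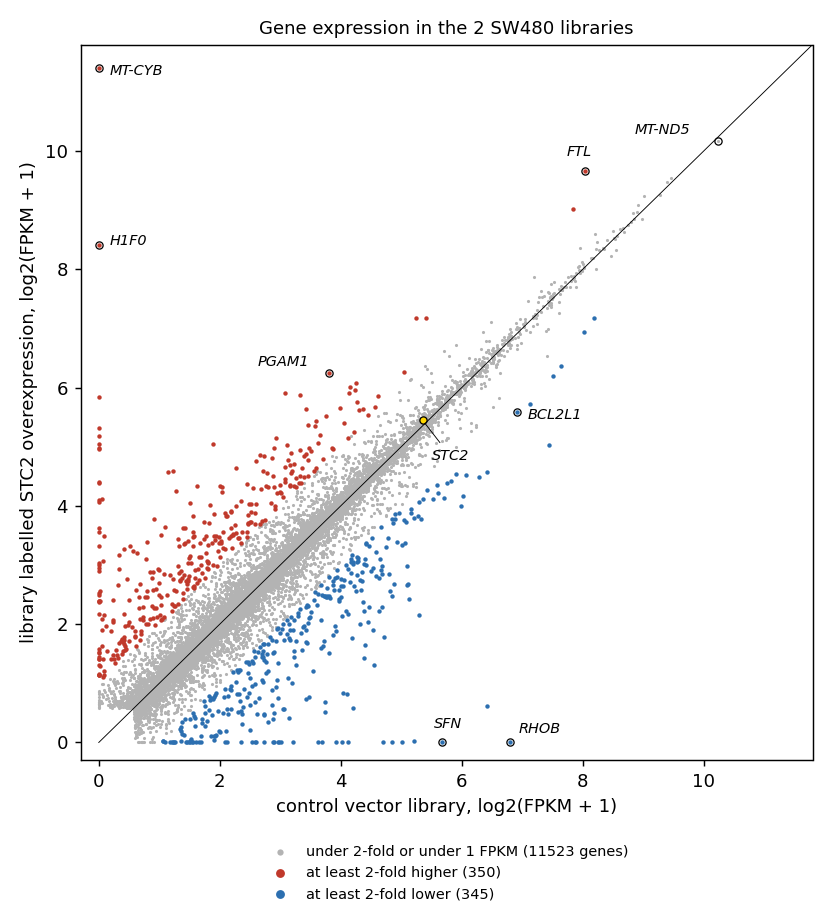
Expression of the 12218 listed genes in the control library (horizontal axis) and in the library labelled STC2 overexpression (vertical axis), both as log2(FPKM + 1), with the line of equality. Red points are the 350 genes at least 2-fold higher and blue points the 345 at least 2-fold lower. STC2 (yellow) lies near the line of equality, and points along either axis are genes listed at 0 in 1 library.

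The genes with the highest levels in the library labelled STC2 overexpression relative to control were mostly listed at 0 in the control library. MT-CYB, the mitochondrially encoded cytochrome b of respiratory complex III, was listed at 0 in control and at 2720 FPKM in the other library. H1F0, a linker histone associated with differentiated cells, was listed at 0 and at 341 FPKM. HNRNPH2, a splicing regulator, was listed at 0 and 56.2 FPKM, CCDC85B at 0 and 38.8 FPKM, and RRAGA, a Rag GTPase that signals amino acid supply to mTORC1, at 0 and 35.4 FPKM. CENPB, a centromere protein, was listed at 0 and 30.3 FPKM. The readthrough gene SENP3-EIF4A1 was listed at 0 and 32.0 FPKM; it overlaps SENP3, at 20.3 and 9.29 FPKM, and EIF4A1, at 93.8 and 80.6 FPKM, so its value is uncertain. RNF113A was listed at 0 and 20.3 FPKM, TSPYL1 at 0 and 19.9 FPKM, SMIM10 at 0 and 16.1 FPKM, CSNK2A3 at 0 and 15.7 FPKM, and UBQLN2, a ubiquilin that shuttles proteins to the proteasome, at 0 and 11.4 FPKM. CSNK2A3 is an intronless copy of CSNK2A1, with which it may share reads. NXPH4 was at 0.042 FPKM in control and at 16.3 FPKM in the other library, a log2 fold of 4.05 that was 6.85 with a pseudocount of 0.1 FPKM and 2.08 with one of 5 FPKM.

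The genes with the lowest levels relative to control showed the mirror picture. RHOB, a small GTPase of endosomal trafficking, was at 110 FPKM in control and listed at 0 in the library labelled STC2 overexpression. SFN, the 14-3-3 sigma protein of the p53-dependent G2 checkpoint, was at 49.8 FPKM and listed at 0. PRNP, the prion protein gene, was at 84.4 and 0.52 FPKM, a log2 fold of -5.81, and the zinc finger gene ZBED2 was at 35.9 and 0.017 FPKM, a log2 fold of -5.18 (-8.26 and -3.03 with those pseudocounts). The histone genes HIST3H2A and HIST2H2BE were at 31.1 and 11.4 FPKM in control, and both were listed at 0 in the other library. MT-ND2, a mitochondrially encoded subunit of complex I, was at 25.02 FPKM and listed at 0. IRS2, an adaptor of the insulin and IGF1 receptors, was at 14.1 FPKM and listed at 0. RNF26 (27.7 FPKM), C17orf96 (16.5 FPKM), THAP11 (15.3 FPKM) and DOLK, the dolichol kinase (11.97 FPKM), were likewise listed at 0 in the library labelled STC2 overexpression. The zinc finger genes ZNF770 and ZNF358 had log2 folds of -3.62 and -3.28.

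A listed 0 need not mean a silent gene, since RRAGA and CENPB are expressed in nearly all cells and MT-CYB in all cells with mitochondria. The control library listed 50 genes at 0 and the other library 45. Of the 14 genes named as highest, 13 were listed at 0 in control and 11 have a single exon in their longest annotated transcript. Of the 14 named as lowest, 10 were listed at 0 in the library labelled STC2 overexpression and 9 have a single exon in that transcript. The share of 2-fold genes rose with the part of the longest annotated transcript that 1 exon takes up. It was 0.99% among the 4442 genes whose longest exon made up at most 50% of the transcript (21 higher, 23 lower), 7.03% among the 4581 genes between 50% and 80% (168 higher, 154 lower) and 15.7% among the 2070 genes above 80% (161 higher, 163 lower). Among the 278 genes whose longest annotated transcript is a single exon it was 27.0%. Other transcripts of these genes may have more exons.

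**Figure D2:**
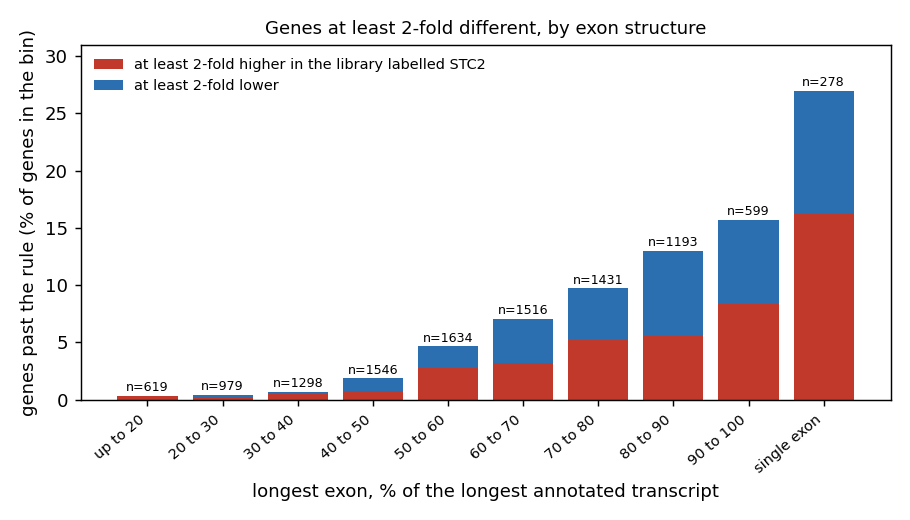
Percentage of genes at least 2-fold higher (red) or lower (blue) in the library labelled STC2 overexpression, by the share of the longest annotated transcript that its longest exon makes up, with the number of genes above each bar. The stacked bars go from 0.32% in the leftmost group of 619 genes to 27.0% for genes whose longest annotated transcript is a single exon.

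The named-gene rule was repeated, after the data had been seen, on genes above 0 in both libraries whose longest exon made up at most 50% of the transcript. FTL, the ferritin light chain that stores iron, was at 262 FPKM in control and 814 FPKM in the library labelled STC2 overexpression, a ratio of 3.11. SLC9A3R1, the scaffold NHERF1 of apical membrane proteins, was at 7.73 and 26.4 FPKM (log2 fold 1.65), and C1QBP, a mitochondrial matrix protein, was at 34.4 and 69.3 FPKM (log2 fold 0.99). The translation regulator PAIP2 had a log2 fold of 1.32, AIDA 1.33, MID1IP1 1.40, CMTM8 1.21, PHPT1 1.09, TTLL12 1.05, EMC7 1.03, TCAF1 1.01 and ALPP 0.94. The remaining genes of this group were LINC00116, at 0.048 and 7.43 FPKM, and the readthrough gene ATP5J2-PTCD1, at 1.66 and 9.24 FPKM.

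In the other direction, CST7, the cysteine protease inhibitor cystatin F, was at 55.6 FPKM in control and 20.5 FPKM in the library labelled STC2 overexpression (log2 fold -1.39). YWHAB, the 14-3-3 beta protein, was at 59.1 and 22.2 FPKM (log2 fold -1.37), and BOD1, which acts in chromosome alignment, was at 32.9 and 12.3 FPKM (log2 fold -1.35). SCARB2, a lysosomal membrane protein, had a log2 fold of -1.32, and AMD1, an enzyme of polyamine synthesis, one of -1.18. The log2 folds of COPS9, AGPAT1, FOXJ2, C4orf48, GNPDA1 and MRPL10 lay between -1.62 and -1.16. CTC-260F20.3 and RP11-864I4.1 had log2 folds of -1.65 and -1.29. The longest exons of these lower genes ranged from 33.1% (C4orf48) to 49.9% (BOD1) of the transcript, several of them close to the 50% limit. Between 40% and 50%, 1.88% of genes differed at least 2-fold, against 0.69% between 30% and 40%.

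Gene groups fixed before the data were examined gave 36 lists with at least 3 measured members. Their median log2 folds ranged from -0.07 to 0.30. The medians of 2 lists, both above, lay outside the central 95% of 10000 random lists matched on expression, where chance alone would place 1.8 of 36. Of the 524 distinct genes measured in the lists, 16 were at least 2-fold higher and 20 at least 2-fold lower. For most members named below the longest-exon share is not given. The rise of 2-fold calls with that share limits the reading of their folds too.

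The 19 measured apoptosis regulators had a median log2 fold of 0.19, against -0.08 to 0.11 for the random lists. Of these members 2 have a longest exon of at most 50% of the transcript, and random lists also matched on that share, added after the data had been seen, gave -0.09 to 0.11. The anti-apoptotic gene MCL1 was at 11.7 FPKM in control and 35.6 FPKM in the library labelled STC2 overexpression (log2 fold 1.53), and the anti-apoptotic BCL2L2 had a log2 fold of 1.24. BCL2L1, the gene of BCL-XL, differed in the other direction, with 119 and 47.2 FPKM (log2 fold -1.32), and CFLAR, an inhibitor of caspase 8, had a log2 fold of -0.47. In all, 3 of the 19 were at least 2-fold different, and 23.39% of random lists matched on level and exon structure had as many. The median of this list was -0.036 when only members with a mean of at least 5 FPKM were taken. The 16 measured p53 targets had a median of 0.16, against -0.10 to 0.12. The death receptor gene TNFRSF10B had a log2 fold of 0.99 and ZMAT3 one of 0.93, whereas CDKN1A, the cell cycle inhibitor p21, was at 24.5 and 6.53 FPKM (log2 fold -1.76) and MDM2, the ubiquitin ligase of p53, had a log2 fold of -0.46. CDKN1A was the 1 member at least 2-fold different; with a pseudocount of 0.1 FPKM there were 3, with TNFRSF10B at 1.10 and ZMAT3 at 1.14. Without members under a mean of 5 FPKM, the p53 target median was 0.14, at the 94.8 percentile of its random lists.

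**Figure D3:**
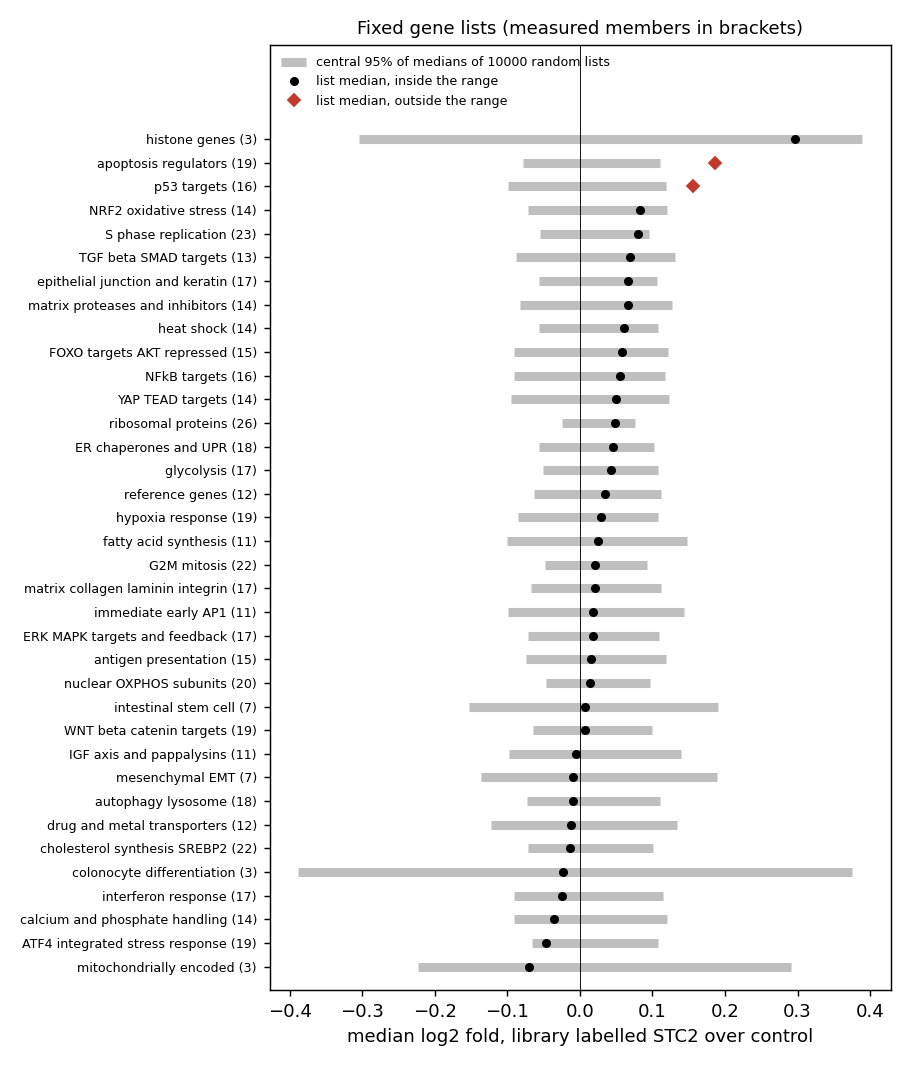
Median log2 fold (library labelled STC2 overexpression over control) of each fixed gene list, with the number of measured members in brackets. Grey bars are the central 95% of the medians of 10000 random lists of the same size matched on expression. The medians of the p53 targets (0.16) and the apoptosis regulators (0.19), drawn as red diamonds, lie to the right of their bars.

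Targets and feedback regulators of the ERK pathway had a median log2 fold of 0.02, but 8 of 17 were at least 2-fold different, 4 in each direction (5 of 17 with a pseudocount of 5 FPKM). DUSP4, a nuclear ERK phosphatase, was at 1.94 and 10.1 FPKM (log2 fold 1.92), and SPRED1, an inhibitor of RAS signalling, was at 1.11 and 6.23 FPKM (log2 fold 1.78). DUSP5, another nuclear ERK phosphatase, was at 27.7 and 4.60 FPKM (log2 fold -2.36), and SPRY4, of the Sprouty feedback inhibitors, was at 21.5 and 6.44 FPKM (log2 fold -1.60).

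Genes of epithelial and mesenchymal state differed little. Of 17 epithelial junction and keratin genes, CLDN4 alone was at least 2-fold higher, at 1.18 and 4.64 FPKM (under 2-fold with a pseudocount of 5 FPKM), and its longest exon makes up 98.1% of the transcript. CLDN7 had a log2 fold of 0.35, CLDN3 one of -0.15 and CLDN1 one of -0.18. None of the 7 measured mesenchymal genes differed by 1.5-fold. ITGA5 had a log2 fold of 0.28 and SNAI1 of 0.16, and TGFBI and VIM, the vimentin gene at 42.1 and 38.0 FPKM, had -0.08 and -0.14. Of 14 matrix proteases and their inhibitors none was 2-fold different. ADAM9 and TIMP1 had log2 folds of 0.65 and 0.42, and PLAU and MMP11 of -0.50 and -0.65.

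Cell cycle genes were near equal as groups. The median of 22 genes of G2 and mitosis was 0.02, with UBE2C at 0.73 and NUSAP1 at 0.50 at the top and AURKA at -0.38 and CCNA2 at -0.75 at the bottom, none of them 2-fold. The median of 23 S phase genes was 0.08. GINS1, a subunit of the replicative helicase, was the 1 member at least 2-fold higher, at 3.27 and 13.8 FPKM. SLBP had a log2 fold of -0.12 and PCNA of -0.43.

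Among 19 WNT targets, the ubiquitin ligase gene ZNRF3, a feedback inhibitor of the pathway, was at least 2-fold higher, at 9.18 and 20.02 FPKM (log2 fold 1.05). ASCL2, a transcription factor of intestinal stem cells, was at 1.004 and 2.33 FPKM, and MYC and CD44 had log2 folds of -0.22 and -0.25. In the hypoxia list, BNIP3L, a mitophagy receptor, was at 10.0 and 40.5 FPKM (log2 fold 1.91) and EGLN3 had a log2 fold of 0.81. MXI1 and NDRG1 had -1.43 and -1.003, and the median over 19 members was 0.03. As many 2-fold members as the 3 of this list were found in 12.93% of random lists matched on level and exon structure. Of 17 glycolysis genes, PGAM1, phosphoglycerate mutase, was at 13.1 and 74.9 FPKM (log2 fold 2.43). The next highest, TPI1, had a log2 fold of 0.38, and the lowest were SLC16A3 (-0.09) and ENO2 (-0.29).

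STC2 is itself induced by stress of the endoplasmic reticulum, and none of 18 genes of its chaperones and the unfolded protein response was 1.5-fold different. SYVN1 and SDF2L1 had log2 folds of 0.47 and 0.24, and EDEM1 and XBP1 of -0.17 and -0.38. Among 19 genes of the ATF4 response, TRIB3, a pseudokinase that binds AKT, was at 5.59 and 23.2 FPKM (log2 fold 1.87). The serine synthesis gene PSAT1 was at 51.0 and 97.6 FPKM (log2 fold 0.92), and CEBPG and CHAC1 had log2 folds of -0.57 and -0.63. The list median was -0.05.

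Stanniocalcins are known for calcium and phosphate balance and for inhibiting pappalysins, the proteases that release IGF from its binding proteins. None of 14 calcium and phosphate handling genes was 2-fold different. STIM1 had a log2 fold of 0.68, ORAI3 of 0.45, SLC20A2 of -0.37 and ORAI1 of -0.43. Of 11 genes of the IGF axis, the insulin receptor substrate IRS1 was at 2.75 FPKM in control and 0.077 FPKM in the library labelled STC2 overexpression (log2 fold -1.80, and -0.61 with a pseudocount of 5 FPKM), and IRS2 is listed at 0 in the latter. Of random lists matched on level and exon structure, 16.5% had as many as 2 members past the 2-fold rule. IGF2 and IGF1R had log2 folds of 0.73 and 0.17. None of 12 drug and metal transporters was 1.5-fold different. ABCC3 and MVP had log2 folds of 0.20 and 0.10, and ABCC5 and ATP7A of -0.17 and -0.20.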

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

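The limits on the longest exon and to genes above 0 in both libraries, the matching on the longest exon, and the other settings for the ERK list were chosen after seeing the data. The log2 fold of STC2 stayed between 0.07 and 0.09 under both other pseudocounts and both scalings. The counts of 350 higher and 345 lower genes became 130 and 131 with a pseudocount of 5 FPKM, which shrinks the folds of weak genes, and 725 and 661 with the 1.5-fold rule. They became 21 and 23 among genes with a longest exon of at most 50% of the transcript, a share of 0.99% against 6.24% among all genes counted. The other settings kept both counts within 1.5 times, with 519 and 470 at a pseudocount of 0.1 FPKM, 246 and 243 at a filter of 5 FPKM, and 315 and 310 among genes above 0 in both libraries. With members of a mean of at least 5 FPKM, the median of the apoptosis regulators turned to -0.036 (12.8 percentile), and that of the p53 targets was 0.14 (94.8 percentile); both lists then have fewer members. With the longest-exon limit the p53 median was 0.14 (96.2 percentile), and 0 of the 28 lists that kept at least 3 members stood apart; the apoptosis list kept 2 members and was not among them. With random lists matched on the longest exon as well, the same 2 of 36 lists stood apart, the apoptosis regulators at the 99.8 percentile and the p53 targets at 99.4. STC2 aside, the naming rule, its repeat and up to 4 members of each list gave 168 genes with a fold. Under 4 settings each, 633 folds stayed on their side of the 2-fold rule, 29 dropped under it, 27 of these with the pseudocount of 5 FPKM, 10 passed it with the pseudocount of 0.1 FPKM, and no fold of at least 2 turned direction. Those that dropped under it with 5 FPKM include the log2 folds of SPRED1 (0.88), ZNRF3 (0.82), BCL2L2 (0.76), MXI1 (-0.88), NDRG1 (-0.69), IRS1 (-0.61), CLDN4 (0.64), STARD4 (-0.91), MSMO1 (-0.68) and IFIT3 (-0.43). Those that passed it with 0.1 FPKM were CCL2 (-1.74), EGLN3 (1.21), ASCL2 (1.14), ZMAT3 (1.14), CHAC1 (-1.14), TNFRSF10B (1.10), FOS (1.09), ALPP (1.07), C1QBP (1.01) and CEBPG (-1.01). The size of the log2 fold moved by over 1.5 times for 20 of the 57 such genes of at least 2-fold, all 20 with the pseudocount of 5 FPKM and 5 also with that of 0.1 FPKM, so the sizes of folds with a low value in 1 library depend on it. The number of 2-fold members of the ERK list was 8 with a pseudocount of 0.1 FPKM and with both scalings, and 5 with one of 5 FPKM. Without counts, the share of any difference that is due to depth could not be tested.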

Other observations

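The list medians and their random lists were planned; the counts of 2-fold members against matched random lists, and the tests of explanations for the 3 patterns weighed here, were chosen after the results had been seen. The medians of the other gene groups lay inside the range of their random lists, and members are given here as values. Of 18 autophagy and lysosome genes, MAP1LC3B, the gene of LC3B, was at 19.1 FPKM in control and 3.03 FPKM in the library labelled STC2 overexpression (log2 fold -2.32), and its relative GABARAPL2 was at 19.1 and 4.97 FPKM (log2 fold -1.75), while GABARAPL1 and ATG7 had log2 folds of 0.34 and 0.27. Among random lists matched on level and exon structure, 21.65% had as many 2-fold members as these 2. Of 22 cholesterol synthesis genes, the sterol carrier STARD4 was at 13.1 and 4.58 FPKM (log2 fold -1.33) and MSMO1 at 9.01 and 3.77 FPKM (log2 fold -1.07), and NSDHL and EBP had 0.64 and 0.27; 30.05% of matched random lists had as many as 2, and neither STARD4 nor MSMO1 was 2-fold different with a pseudocount of 5 FPKM. None of 11 fatty acid synthesis genes was 2-fold different, and the desaturase SCD was at 47.4 and 26.2 FPKM (log2 fold -0.83). The small heat shock protein HSPB1 was at 139 and 51.5 FPKM (log2 fold -1.41), with SERPINH1 at 0.57 and HSP90AA1 at -0.22. Of 13 TGF-beta targets, the pseudoreceptor gene BAMBI had a log2 fold of -1.15 and the inhibitory SMAD7 one of 0.65. Of 17 interferon response genes, IFIT3 was at 2.02 and 0.21 FPKM (log2 fold -1.32), BST2 had 0.53, and OAS3 had -0.15. Of 16 NF-kB targets, ICAM1 and CCL2 had log2 folds of -0.80 and -0.93 (CCL2 -1.74 with a pseudocount of 0.1 FPKM, past the 2-fold rule), and BIRC3 and NFKB1 had 0.40 and 0.24.

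Among genes often used as references, HPRT1 was at 74.1 and 39.6 FPKM (log2 fold -0.89), while TBP and TFRC had 0.45 and -0.42. None of 26 ribosomal protein genes was 1.5-fold different, with RPS2 at 0.39, RPL11 at -0.21 and RPLP1 at -0.42. Of the 3 mitochondrially encoded genes listed, MT-ND5 was at 1204 and 1147 FPKM, although MT-CYB was listed at 0 in control and MT-ND2 at 0 in the library labelled STC2 overexpression. Of the colonocyte markers 3 were measured, with MUC13 at 3.11 and 3.79 FPKM, CDX2 at 6.56 and 6.44 FPKM and VIL1 at 5.73 and 5.51 FPKM. Markers of other cell types were few and near equal in both libraries. COL1A1 was at 1.84 and 2.07 FPKM, ACTA2 at 2.38 and 2.55 FPKM and CD14 at 1.03 and 1.32 FPKM. The blood markers HBA1 and HBA2 were measured as well, with log2 folds of 0.09 and 0.17, and no endothelial marker was listed.

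The genes at least 2-fold different were concentrated in genes made mostly of 1 exon, about equally in both directions. Weak expression alone does not account for them, since 4.84% of the 1591 genes with a mean of at least 20 FPKM differed at least 2-fold. The 95% Wilson interval over genes, taken as independent, was 3.89% to 6.01%. The share was 5.88% of 4691 genes with a mean of 1 to 5 FPKM, where the added 1 FPKM shrinks the folds. The 2 shares are thus not on a like footing, and without counts the counting noise itself was not measured. A candidate explanation is the quantification of genes made mostly of 1 exon. In each of 5 ranges of expression, the share of 2-fold genes was at least 9.93 times as high with a longest exon above 80% of the transcript as with one up to 50%. Of 70 genes listed at 0 in 1 library and with at least 1 FPKM in the other, 68 had a known exon structure. Of these, 51 had a single exon in their longest annotated transcript. The step that would act on such genes is not known, and genes with few exons differ in other ways, such as the stability of their transcripts, that were not tested. A response of the cells to STC2 stays open, because these values cannot decide it. Of the genes with a longest exon up to 50%, 0.99% still differed at least 2-fold. Without replicates this share cannot be set against the spread between control libraries. It also rose within this group, from 0.32% for a longest exon up to 20% to 1.88% from 40% to 50%. STC2 itself was not higher by the rule of size.

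STC2 was not higher by the rule of size in the library labelled STC2 overexpression. A swap of an overexpressing and a control library would put STC2 clearly lower in the library labelled STC2 overexpression, and its log2 fold was 0.0905. The spread among genes of like level and structure leaves this open: for 606 genes with a mean of at least 20 FPKM and a longest exon of 50% to 80% of the transcript (66.1% for STC2), the central 95% of log2 folds ran from -1.32 to 1.43. Loss of STC2 reads in quantification could not be decided from these values. Of these 606 genes, 52 (8.58%) differed at least 2-fold, which does not show whether STC2 reads were lost. That STC2 RNA was not raised in this culture stays possible as well; read coverage along STC2 was not analysed here.

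The ERK list held more 2-fold members than any other of the 36 lists, 8 of 17. Besides DUSP4, SPRED1, DUSP5 and SPRY4 these were, named after their values were seen, SPRED2 (5.38 and 18.6 FPKM), EREG (0.33 and 1.91 FPKM), FOSL1 (40.2 and 16.4 FPKM) and HBEGF (4.38 and 1.58 FPKM). Mean level and longest-exon share, as matched here, do not account for the number. Of 10000 random lists matched on both, 0 had as many, against a mean of 1.33. With a pseudocount of 5 FPKM, where 5 members were 2-fold different, 4 of 10000 had as many. Other traits of exon structure were not matched, and 4 of the 17 members have a longest exon of at most 50% of the transcript. A change of all ERK targets in 1 direction did not show in the list as a whole, where 9 members lay above 0 and 8 below. The median of 0.02 lay inside the -0.07 to 0.11 of random lists matched on expression. Random lists hold fewer 2-fold members, so that range may be too narrow for a list with 8 of 17. A shared shift is thus neither shown nor excluded by the median. A change of some of the targets in 1 direction stays open. The 4 members on the other side were reached by at most 42 of 10000 random lists in the direction left to noise. That comes to 15.1% when multiplied by the 36 lists among which this one was picked. A response that moves individual ERK regulators in both directions may remain as well, as may a feature of these transcripts other than the longest-exon share, and replicate libraries would be needed to tell these from the spread between cultures.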
